A study of Mus musculus with 6 samples.

How the data were processed

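Pancreatic islets of wild-type NOD mice and of NOD mice lacking Tet2 were profiled by single-cell RNA sequencing in 6 libraries. Of these, 4 used a 5' chemistry (2 WT, 2 KO) and 2 a 3' chemistry (1 WT, 1 KO). Each library pooled the islets of 4 to 6 mice, and 2 to 3 pools per genotype are described. The Tet2 allele came from a B6 line after more than 14 generations of backcross to NOD. The number in a library's title is called its set, and nothing in the labels ties a WT set to the KO set of the same number. The protocol text describes capture of single nuclei for chromatin accessibility rather than the RNA libraries, so how the cells were captured is not stated.

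The deposited values are raw UMI counts per gene and cell barcode, per the file headers, for 32285 genes, of which 38 symbols carry more than 1 identifier. The authors name Cell Ranger 7.0.1, Seurat 4.3.0.1 and the mm10 genome in their notes, without saying which step each did. Every barcode held 500 or more UMIs. Gene positions came from GENCODE vM21 on GRCm38.

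Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored within each library against simulated pairs of cells, by code written in the manner of Scrublet, and a share of 0.8% for each 1000 barcodes of the library was removed. Counts were scaled to 10000 per cell and log-transformed. Within each chemistry 2000 variable genes and 30 principal components were used, with 20 neighbours and Leiden clustering at resolution 1.0 (python-igraph 0.11.9, leidenalg 0.10.2). T cells, NK cells and innate lymphoid cells were clustered again. Clusters were named from marker genes alone, without regard to genotype, and clusters that no marker set fitted were left unnamed. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.

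Counts of each class were summed per library, where the library held at least 20 cells of the class. This left 16 classes, 10 with all 6 libraries and 6 with the 4 5' libraries. Each class was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries scaled by TMM, and genotype tested by the robust quasi-likelihood F test with chemistry as a covariate. The p-values were adjusted by the Benjamini-Hochberg method over the genes of a class, and a gene passed at an adjusted p under 0.05. The error beside a log2 fold change is its size divided by the square root of F. Levels per library are CPM, counts scaled by the library's total over the class without TMM. Fewest and most counts per library in a class ranged from 17719100 and 91685500 in beta cells to 52402 and 225362 in NK cells or innate lymphoid cells.

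Shares of 19 classes among all kept cells, and of 11 immune classes among immune cells, were tested with the same edgeR model on cell numbers. The share of all immune cells was compared by an exact permutation test within chemistry over 12 arrangements. Of 33 gene lists written down in advance, 30 had 5 or more measured members in beta cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera with an estimated correlation was an alternative. For each list the text gives the members that passed over all genes and those that passed when p was adjusted over the list alone.

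Genes were named by a rule. They had an adjusted p under 0.05 and all KO libraries on the same side of all WT libraries within each chemistry. The 12 with the lowest p per direction were taken in beta cells, 8 per direction in CD8 T, CD4 T and B cells and in macrophages, and 3 in other classes. Immunoglobulin and T cell receptor segments, predicted genes, ribosomal and mitochondrial genes, Xist and Y-linked genes were passed over. Genes tied to the question of the series, such as Tet2, Ddit3, Hspa5, Ins1, Ins2, Cxcl10, Ifng, Foxp3 and Il1b, were named whatever their value, as were 2 to 4 members with the lowest p of each list discussed. Where fewer than 3 genes passed in CD8 T, CD4 T or B cells or macrophages, the 5 with the lowest p were named as not passing. The values of a few genes that this rule takes in are not reported here, while counts of genes include them. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Which lists the text discusses was chosen afterwards, and so were cluster names.

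Alternatives were DESeq2 1.42.0, limma-voom, no TMM, no filter on low counts, the 5' libraries alone, other cell filters and a Leiden resolution of 2.0. Others kept doublets or used a filter that leaves out genes whose level in a class is under 5% of that in the class where it is highest. Further ones left out 1 library at a time, treated chemistry and set as a block, or kept beta cells without UMIs of other classes. The edgeR test was also tested on simulated data with 200 changed genes per class, first run after the real results were seen. It recovered 79% of changes of 2-fold and 93% of changes of 4-fold in beta cells, 60% and 93% in macrophages, 48% and 84% in B cells, 46% and 85% in CD8 T cells, and 28% and 81% in CD4 T cells. A list moved in simulated data had adjusted p = 0.0263 by camera with an estimated correlation. There 0 of 29 others were called, but this bounds no false calls: other splits of the real libraries gave up to 22.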

Results

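Pancreatic islets were compared between wild-type (WT) NOD mice, a strain in which T cells attack the insulin-producing beta cells, and NOD mice lacking Tet2 (KO), an enzyme that oxidises 5-methylcytosine in DNA. The series title asks how Tet2 bears on stress of the endoplasmic reticulum (ER), death of beta cells and autoimmunity. Single-cell RNA libraries were made with a 5' chemistry (2 WT and 2 KO libraries, numbered set 1 and set 2) and with a 3' chemistry (1 WT and 1 KO library). Each library pooled the islets of 4 to 6 mice, so the unit of replication is a pool, with 3 WT and 3 KO libraries. The labels do not say whether the 3' libraries came from other pools than the 5' libraries. If pools were shared, p-values over all 6 libraries are too small. The design text gives an age of 10 to 13 weeks, whereas the protocol counts 10 to 13 weeks after a step written as BTM, and a treatment text speaks of mice that donated bone marrow. Whether the islets came from recipients of marrow, and of which genotype that marrow then was, is not stated. In every immune class WT and KO therefore stand for the label of the library, which need not be the genotype of the immune cells.

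The WT 5' libraries held 50425523 UMIs (set 1) and 71588449 UMIs (set 2), and the KO 5' libraries 101554880 (set 1) and 82897835 (set 2). The WT 3' library held 117359711 UMIs and the KO 3' library 121713971. After filtering, 14403 and 9570 cells were kept in the WT 5' libraries, 13227 and 13707 in the KO 5' libraries, 10702 in WT 3' and 7722 in KO 3'. Median UMIs per kept cell were 1118 and 3268 in the WT 5' libraries against 4186 and 3314 in the KO 5' libraries, and 5942.5 in WT 3' against 13252 in KO 3'. Within beta cells alone depth was closer, with medians of 9112, 16175, 10692 and 8996 UMIs in the 5' libraries in the same order.

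Tet2 itself (ENSMUSG00000040943) lies on the minus strand of chromosome 3 at 133463679 to 133545139 (GRCm38, GENCODE vM21). In beta cells it stood at 8.75 and 7.80 CPM (counts scaled by the library's total in the class) in the WT 5' libraries, 4.68 and 9.37 in the KO 5' libraries, 27.9 in WT 3' and 25 in KO 3'. Its log2 fold change, KO over WT, was -0.07 ± 0.15 (SE, 3 against 3 libraries, adjusted p = 0.969). The structure of the allele and the position of the reads along the gene were not analysed here, so it stays open whether these levels bear on the genotype labels. Tet1 (-0.17 ± 0.15, adjusted p = 0.895) and Tet3 (-0.06 ± 0.20, adjusted p = 0.981) did not pass the test in beta cells either. Tet2 stood at -1.07 ± 0.49 in CD8 T cells (adjusted p = 0.822), -0.13 ± 0.53 in CD4 T cells (0.985), -0.29 ± 0.35 in B cells (1.00) and -0.10 ± 0.22 in macrophages (0.920). Tet3 stood between -1.02 ± 0.46 in CD4 T cells (adjusted p = 0.706) and 0.17 ± 0.17 in macrophages (0.756).

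Immune cells made up a smaller part of the KO libraries. They were 77.3% and 63.6% of kept cells in the WT 5' libraries against 26.7% and 20.7% in the KO 5' libraries, and 45.3% in WT 3' against 5.30% in KO 3'. B cells fell from 28.7% and 19.7% to 5.14% and 5.09% in the 5' libraries and from 22.6% to 0.609% in the 3' libraries (log2 ratio -3.14 ± 0.75, SE, n = 3 against 3, adjusted p = 0.0208). Cycling T cells (-2.10 ± 0.42, adjusted p = 0.0163), CD4 T cells (-2.37 ± 0.57, adjusted p = 0.0208) and CD8 T cells (-1.74 ± 0.43, adjusted p = 0.0208) fell as well. So did T cells of no further class (other T cells; -2.59 ± 0.48, adjusted p = 0.0163), regulatory T cells (-1.62 ± 0.49, adjusted p = 0.0357), NK cells or innate lymphoid cells (NK/ILC cells; -1.33 ± 0.43, adjusted p = 0.0421) and conventional dendritic cells (-1.18 ± 0.40, adjusted p = 0.0446). Glucagon-producing alpha cells rose (1.19 ± 0.41, adjusted p = 0.0446), as did cycling beta cells (1.75 ± 0.48, adjusted p = 0.0286). The last class rests on 15 and 8 cells in the WT and 26 and 44 in the KO 5' libraries, and on 4 in WT 3' and 17 in KO 3'. Without doublet removal its ratio was 0.59, without a call. Beta cells took 12.9% and 21.2% of the WT against 43.5% and 36.1% of the KO 5' libraries, and 35.9% of WT 3' against 65.7% of KO 3' (1.11 ± 0.40, adjusted p = 0.0517). The other 8 of the 19 classes did not pass, among them endothelial cells (1.24 ± 0.47, adjusted p = 0.0545), delta cells (0.70 ± 0.38, adjusted p = 0.143) and macrophages (-0.59 ± 0.39, adjusted p = 0.198). Shares sum to 100%, so a fall of some classes raises the others. Cells in clusters left unnamed count in the total. Those outside the immune cells were 1.41% and 2.06% in the WT and 3.43% and 18.6% in the KO 5' libraries, 0.86% in WT 3' and 4.325% in KO 3'. Those counted as immune cells were a further 2.91%, 5.12%, 1.63%, 1.76%, 1.925% and 0.414% in the same order. The log2 ratio of all immune cells was -1.58 in the 5' and -3.10 in the 3' libraries (two-sided exact permutation p = 0.167, the smallest 12 arrangements allow).

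Of these shares, other T cells kept their call without any of the 6 libraries. Without KO 5' set 1 the calls of B (-3.35), CD4 T (-2.64), regulatory T (-1.89), NK/ILC (-1.54) and alpha cells (1.04) were lost. Without KO 5' set 2 CD4 T (-2.42), CD8 T (-1.66), cycling T (-2.05) and regulatory T cells (-1.63) lost theirs. So did NK/ILC (-1.18), dendritic (-1.03), alpha (1.18) and cycling beta cells (1.63). Without WT 5' set 2 CD8 T (-1.87), regulatory T (-1.78), NK/ILC (-1.13), dendritic (-1.24), alpha (1.13) and cycling beta cells (1.75) lost theirs. Cycling B (-3.48) and ductal cells (3.50) then passed. Without WT 5' set 1 alpha (1.05) and dendritic cells (-1.18) lost theirs. Without either 3' library CD8 T (-1.43), regulatory T (-1.13), NK/ILC (-1.27), dendritic (-1.06) and cycling beta cells (1.44) lost theirs.

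Among immune cells alone, macrophages took a larger part in KO. They were 6.52% and 8.77% of immune cells in the WT 5' libraries against 17.3% and 16.1% in the KO 5' libraries, and 6.51% in WT 3' against 29.1% in KO 3' (1.46 ± 0.34, adjusted p = 0.00146). B cells fell from 37.2% and 30.9% to 19.3% and 24.6% in the 5' libraries and from 49.8% to 11.5% in the 3' libraries (-1.09 ± 0.34, adjusted p = 0.0177). The other 9 of 11 immune classes did not pass, including dendritic cells (0.86 ± 0.34, adjusted p = 0.0577), CD4 T cells (-0.31 ± 0.34, adjusted p = 0.459) and CD8 T cells (0.30 ± 0.33, adjusted p = 0.459). The macrophage call was lost without WT 5' set 1 (1.43). The B cell call was lost without WT 5' set 1 (-1.18), WT 5' set 2 (-1.32), KO 5' set 1 (-1.10), WT 3' (-0.63) or KO 3' (-0.63).

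**Figure D1:**
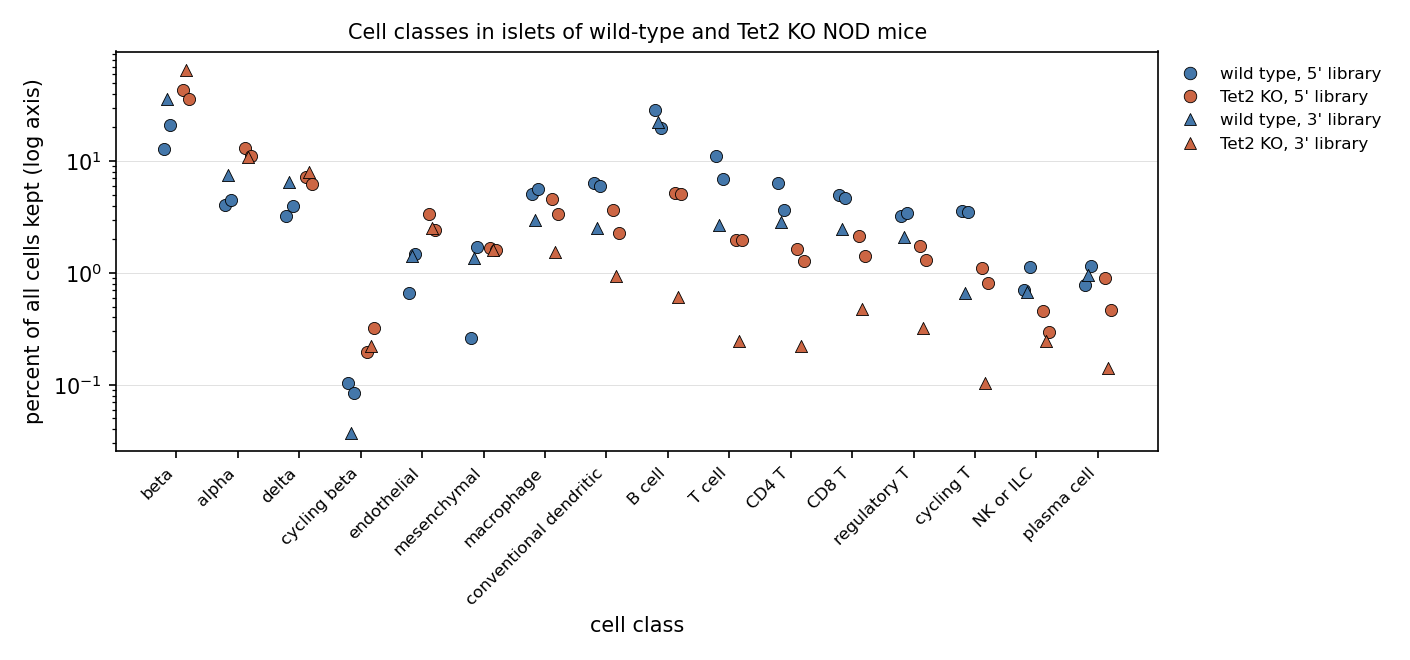
Share of each cell class among all kept cells, in percent on a log axis, for each of the 6 libraries (blue, WT; orange, KO; circles, 5'; triangles, 3'). B cells lie between 19.7% and 28.7% in the WT libraries and between 0.609% and 5.14% in the KO libraries.

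Beta cells of KO islets expressed fewer transcripts of interferon response and antigen presentation. Of 14288 genes tested in 3 WT and 3 KO libraries, 24 were higher and 290 lower. Serping1, an interferon-induced inhibitor of complement C1, fell from 175 and 109 CPM to 21.8 and 31.3 in the 5' libraries and from 53.1 to 9.28 in the 3' libraries (log2 fold change -2.30 ± 0.19, adjusted p = 0.00023). Irf8, an interferon-induced transcription factor, fell by 2.73 ± 0.26 on the log2 scale (adjusted p = 0.00054). B2m, the invariant chain of class I molecules of the major histocompatibility complex (MHC), was at 666 and 425 CPM in the WT and 120 and 192 CPM in the KO 5' libraries, and at 233 against 41.9 in the 3' libraries (-1.88 ± 0.23, adjusted p = 0.0029). The lower genes with the lowest p also held Serpina3i (-2.27 ± 0.24), Dock2 (-2.77 ± 0.32), H2-Q1 (-1.38 ± 0.17), Ly75 (-1.90 ± 0.24), Runx1 (-2.51 ± 0.32), Tifa (-1.13 ± 0.15) and Cytip (-3.12 ± 0.40). B2m aside, only Tifa of these reached 5% of its highest level in any class. Without KO 5' set 1 the call of B2m (-1.88) was lost. Without doublet removal Irf8 (-2.16), Dock2 (-1.96), Runx1 (-2.27) and Cytip (-2.30) did not pass. In beta cells holding no UMI of 6 markers of other classes (Ptprc, Cd3e, Cd79a, Gcg, Sst and Ppy) Irf8 (-3.23) and Ly75 (-1.46) did not pass, and Dock2, Runx1 and Cytip had too few counts to be tested.

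Of 31 measured genes of the interferon-gamma response, 14 fell and none rose when p was adjusted over all genes (28 fell adjusted over the list alone), with a median of -2.51. Among them were the inflammatory caspases Casp4 (-3.38 ± 0.44, adjusted p = 0.0015) and Casp1 (-3.04 ± 0.41, adjusted p = 0.0019) and the guanylate-binding protein Gbp5 (-2.72 ± 0.28, adjusted p = 0.0019). Of 29 genes of the type I interferon response, 16 fell (27 adjusted over the list alone; median -1.55), with Irf7 at -1.36 ± 0.20 (adjusted p = 0.0027), Oas2 at -2.17 ± 0.34 (0.0033) and Ifit2 at -3.56 ± 0.55 (0.0058). Of 19 MHC class I presentation genes, 9 fell (18 adjusted over the list alone; median -1.34), such as H2-Q4 (-1.21 ± 0.14, adjusted p = 0.00078), H2-T22 (-1.67 ± 0.18, 0.0011), H2-K1 (-1.61 ± 0.20, 0.0018) and H2-D1 (-1.30 ± 0.18, 0.0018). Of 9 MHC class II genes, 6 fell (9 adjusted over the list alone; median -2.66), led by H2-DMb2 (-2.71 ± 0.26, adjusted p = 0.00023) and H2-Eb1 (-2.32 ± 0.23, 0.0025) and with Ciita, the class II transactivator, at -2.54 ± 0.39 (0.0029). Of 22 NF-kB and cytokine response genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.47). The fallen ones were the adhesion molecules Vcam1 (-2.89 ± 0.53, adjusted p = 0.0090) and Icam1 (-2.35 ± 0.41, 0.0095), with Tnfaip2 (-2.89 ± 0.54, 0.010) and Traf1 (-3.15 ± 0.75, 0.049; named after its values were seen), while Tnfrsf11b, a decoy receptor, rose (1.53 ± 0.36, 0.040). Cxcl10, a chemokine for T cells, did not pass by edgeR (-2.56 ± 0.73, adjusted p = 0.473), while DESeq2 called it (-2.56). All 5 lists were called lower by camera with a preset correlation, and none with an estimated one (adjusted p = 0.122 with an estimated correlation for each). Members of near-identical families, such as H2-Q, Gbp, Ifit and Oas genes, can share reads, so the value of a single member is uncertain. Without KO 5' set 1 the calls of Gbp5 (-2.76), Ifit2 (-3.44), H2-T22 (-1.68), H2-Eb1 (-2.29), Icam1 (-2.36), Tnfaip2 (-2.99), Traf1 (-4.27) and Tnfrsf11b (1.21) were lost. Those of Icam1 (-2.26), Traf1 (-2.62) and Tnfrsf11b (1.40) were lost without WT 5' set 1. That of Traf1 (-2.93) was lost without KO 5' set 2. Vcam1 (-2.38 and -2.38), Tnfaip2 (-2.0 and -2.0), Traf1 (-2.62 and -2.61) and Tnfrsf11b (1.55 and 1.55) lost theirs without WT 3' and without KO 3', and Icam1 without WT 3' (-1.74). Without doublet removal Casp1 (-2.50), H2-DMb2 (-2.09), H2-Eb1 (-1.39), Ciita (-1.84), Icam1 (-1.99), Tnfaip2 (-1.95), Traf1 and Tnfrsf11b (1.32) did not pass, nor did Oas2 (-1.67) and H2-Eb1 (-2.25) in beta cells without UMIs of other classes.

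Transcripts that belong to immune cells fell in the same beta cells. Of 20 such transcripts 11 fell (15 adjusted over the list alone; median -2.54; adjusted p = 0.122 with an estimated correlation), with Ighm at -3.51 ± 0.39 (adjusted p = 0.0015), Ptprc at -2.69 ± 0.34 (0.0015), Cd79b at -3.87 ± 0.49 (0.0016) and Cd3e at -2.34 ± 0.32 (0.0019). Without doublet removal Ighm (-2.56), Ptprc (-1.75), Cd79b (-2.57) and Cd3e (-1.22) did not pass. Beta cells without UMIs of other classes still held immune transcripts that were lower in KO, with a median of -2.42 over 9 (2 fell, 7 adjusted over the list alone), so this choice of cells did not remove immune RNA. In them the median was -2.17 over 27 interferon-gamma genes (5 fell, 25 adjusted over the list alone), -1.26 over 24 type I interferon genes (7 and 21), -1.20 over 19 MHC class I genes (7 and 16) and -2.53 over 6 MHC class II genes (0 and 6). Over 13 NF-kB and cytokine genes it was -0.23, and edgeR called 0 of them over all genes and 0 adjusted over the list alone. Beta cells of the 2 genotypes came from different clusters in part. The cluster led by Iapp, Dapl1 and Gm4841 held 38.4% and 15.4% of the beta cells of the WT 5' libraries against 6.05% and 5.21% of the KO ones, and the 3' cluster led by F830016B08Rik, Gm4841, Iigp1 and Cxcl10 held 18.3% of WT against 2.84% of KO beta cells. The 5' one led by Ins2, Ins1 and Ppp1r1a differed by set: 27.6% (WT) and 73.0% (KO) in set 1, 4.49% and 3.70% in set 2.

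The number of genes changed in beta cells fell from 314 to 159 without WT 5' set 1, 121 without KO 5' set 1 and 203 without WT 3'. It was 200 in the 5' libraries alone (12 higher, 188 lower), 124 without doublet removal, 83 after genes more abundant in other classes were left out, 59 in beta cells without UMIs of other classes and 681 without the low-count filter. With library totals in place of TMM scaling the median of all genes was -0.146, against 0.02 with TMM, and 4 genes were higher and 262 lower.

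**Figure D2:**
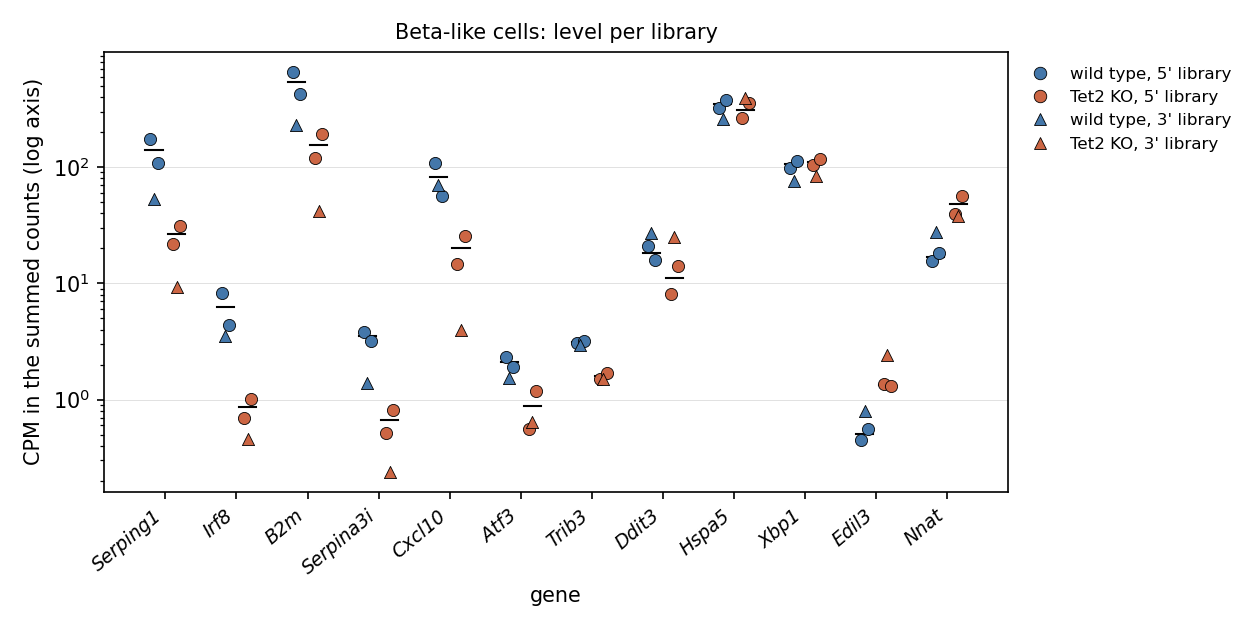
CPM of 12 genes in beta cells, on a log axis, for each library (blue, WT; orange, KO; circles, 5'; triangles, 3'; short black lines, mean of the 2 5' libraries of a genotype). Serping1 was at 175 and 109 CPM in the WT 5' libraries and at 21.8 and 31.3 in the KO 5' libraries.

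Targets of PERK and ATF4 in the ER stress response were lower as a list in KO beta cells. Of 32 targets of PERK and ATF4, the arm that slows translation and induces amino acid genes, 5 fell and none rose (10 fell adjusted over the list alone), and 29 had a negative fold change (median -0.30). The fallen genes were Atf5 (-0.68 ± 0.13, adjusted p = 0.014), Chac1 (-0.75 ± 0.16, 0.025), the stress-induced factor Atf3 (-1.12 ± 0.25, 0.031), Trib3 (-0.80 ± 0.18, 0.032) and Wars (-0.66 ± 0.15, 0.037), the last named after its values were seen. The list was called lower (camera adjusted p = 4.38e-09, adjusted p = 0.181 with an estimated correlation). Ddit3, which encodes CHOP (-0.36 ± 0.16, adjusted p = 0.544), and Atf4 itself (-0.11 ± 0.14, adjusted p = 0.938) did not pass. In beta cells without UMIs of other classes the median of 29 targets was -0.27, with 0 fallen over all genes and 6 adjusted over the list alone. None of the 5 fallen genes passed without WT 5' set 1 (Atf5 -0.59, Chac1 -0.58, Atf3 -1.03, Trib3 -0.81, Wars -0.47). Neither did they without WT 3' or KO 3' (-0.65, -0.75, -1.09, -0.74 and -0.64 in the same order for either), nor in the 5' libraries alone. Without doublet removal Chac1 (-0.76), Atf3 (-0.92) and Wars (-0.64) did not pass. Without KO 5' set 1 Chac1 (-0.65), Atf3 (-0.97), Trib3 (-0.89) and Wars (-0.67) did not pass. Trib3 did not pass without WT 5' set 2 (-0.82) or KO 5' set 2 (-0.74).

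None of the 28 genes of the IRE1 and XBP1 response and none of the 23 ER chaperones and ATF6 targets passed on their own by edgeR, over all genes or adjusted over the list alone. The IRE1 and XBP1 list was called higher (25 of 28 members above 0, median 0.13, camera adjusted p = 0.018, adjusted p = 0.657 with an estimated correlation), and without TMM scaling its median was -0.04, above the -0.146 of all genes there. The ATF6 list was also called higher (median 0.08, camera adjusted p = 0.0384, adjusted p = 0.657 with an estimated correlation), with a median of -0.09 and no call without TMM scaling. Hspa5, the main ER chaperone, stood at 0.25 ± 0.16 (adjusted p = 0.807). Xbp1 stood at 0.27 ± 0.14 (adjusted p = 0.658). The members with the lowest p were Sec23b (0.29 ± 0.14, adjusted p = 0.597) and Ostc (0.30 ± 0.15, 0.603) of the IRE1 list and Hspa13 (0.34 ± 0.14, 0.420) and Derl2 (0.30 ± 0.13, 0.441) of the ATF6 list. Both calls rested on the 3' libraries: in the 5' libraries alone the medians were 0.01 and 0.01, without WT 3' they were 0.03 and 0.03, and without KO 3' 0.04 and 0.04, with no call. Neither list was called in beta cells without UMIs of other classes (0.10 and 0.06). A difference between the IRE1 or ATF6 list and the PERK list was not tested. The ATF6 call was also lost without KO 5' set 1 (0.12).

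Of 29 pro-apoptotic and cell death genes, 4 fell and none rose (4 adjusted over the list alone; median -0.14), among them Mlkl, which carries out necroptosis (-1.74 ± 0.27, adjusted p = 0.0029), the death receptor Fas (-2.14 ± 0.44, 0.018), and the pore-forming Gsdmd (-0.67 ± 0.16, 0.049). The list was called lower (camera adjusted p = 0.0143, adjusted p = 0.351 with an estimated correlation), but not without WT 5' set 1 (-0.14), WT 3' (-0.06) or KO 3' (-0.06), nor in the 5' libraries alone (-0.08). Nor was it called in beta cells without UMIs of other classes, where the median of 26 members was -0.06, with 0 fallen over all genes and 1 adjusted over the list alone. Of 15 anti-apoptotic genes, Bcl2a1b fell (-2.18 ± 0.44, adjusted p = 0.016), and the list was not called (median -0.10, camera adjusted p = 0.0806). It was called lower without WT 3' (-0.10) or KO 3' (-0.10). Mlkl kept its call without each library, but not in beta cells without UMIs of other classes (-1.70). Fas, Gsdmd and Bcl2a1b did not pass without WT 5' set 1 (-1.75, -0.54 and -2.07), KO 5' set 1 (-2.08, -0.74 and -2.03), WT 3' (-2.11, -0.59 and -2.22) or KO 3' (-2.10, -0.59 and -2.21). Txnip, which promotes oxidative death of beta cells, stood at -0.03 ± 0.17.

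Genes of beta cell identity and insulin secretion did not pass in any of 42 cases (median 0.09, and -0.07 without TMM scaling against -0.146 of all genes, camera adjusted p = 0.091), by edgeR over all genes or adjusted over the list alone. Ins2 was at 0.29 ± 0.18 (adjusted p = 0.774), Ins1 at 0.21 ± 0.17 (0.890), Mafa at 0.20 ± 0.14 (0.856) and Pdx1 at 0.14 ± 0.15 (0.927). The lowest p of the list were those of Chgb (-0.48 ± 0.14, adjusted p = 0.127) and Ucn3 (0.46 ± 0.15, 0.174). The list was called higher without KO 5' set 1 (median 0.07). Of 16 genes of dedifferentiation or disallowed in beta cells, Vim (-1.85 ± 0.25, adjusted p = 0.0016), Ldha (-1.82 ± 0.35, 0.018) and Cd24a (-1.0 ± 0.22, 0.031) fell and Nnat rose. The list was not called (median -0.15, camera adjusted p = 0.0751), but was called lower without WT 5' set 2 (-0.38) or KO 5' set 1 (-0.26), and higher in beta cells without UMIs of other classes (0.35 over 10 members, 1 rose and 0 fell). Nnat, which aids insulin secretion, was at 1.31 ± 0.23 (adjusted p = 0.033). Further genes that rose were Edil3 (1.64 ± 0.26, adjusted p = 0.0035), Calb1, a calcium buffer (0.91 ± 0.16, 0.0066), Pak7 (1.43 ± 0.26, 0.0082), Timp2 (0.75 ± 0.15, 0.013), Reln (1.39 ± 0.26, 0.014), Hspb8 (0.65 ± 0.13, 0.019), Rtn1 (0.67 ± 0.14, 0.020), Astn1 (1.14 ± 0.25, 0.024), F13a1 (1.65 ± 0.36, 0.028) and Pcp4 (1.22 ± 0.22, 0.031). Edil3, Timp2 and Vim kept their calls without each library. Vim (-1.33), Ldha (-1.42) and Cd24a (-0.74) lost theirs without doublet removal, and Vim (-1.02) in beta cells without UMIs of other classes. Of the genes named here that rose, only Nnat and Pcp4 passed in those cells, and only Edil3, Nnat and Pcp4 without TMM scaling. When WT 5' set 1 was left out, Nnat (1.15), Reln (1.37), Hspb8 (0.69), Rtn1 (0.67), Astn1 (1.17), F13a1 (1.52), Pcp4 (1.31), Ldha (-1.28) and Cd24a (-0.85) lost theirs. Without KO 5' set 1 Nnat (1.24), Rtn1 (0.61), F13a1 (1.66), Ldha (-1.65) and Cd24a (-0.86) did. F13a1 also did without WT 5' set 2 (1.57). Without WT 3' and without KO 3' Calb1 (0.83 and 0.83), Pak7 (1.48 and 1.49), Reln (1.54 and 1.54), Hspb8 (0.46 and 0.46), Rtn1 (0.59 and 0.59), Astn1 (1.13 and 1.13), Pcp4 (1.37 and 1.38) and Cd24a (-0.93 and -0.93) lost theirs, and F13a1 without KO 3' (2.21). Oxidative phosphorylation genes (median 0.08 over 41, camera adjusted p = 0.0802), islet autoantigens (0.18 over 16, 0.135) and cell cycle genes (-0.16 over 19, 0.18) were not called. Oxidative phosphorylation was called higher without WT 3' (0.15) or KO 3' (0.15). In all, camera with the preset correlation called 16 of 30 lists in beta cells, 7 of them lists of immune cells, against 0 with an estimated correlation and 0 by fry.

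**Figure D3:**
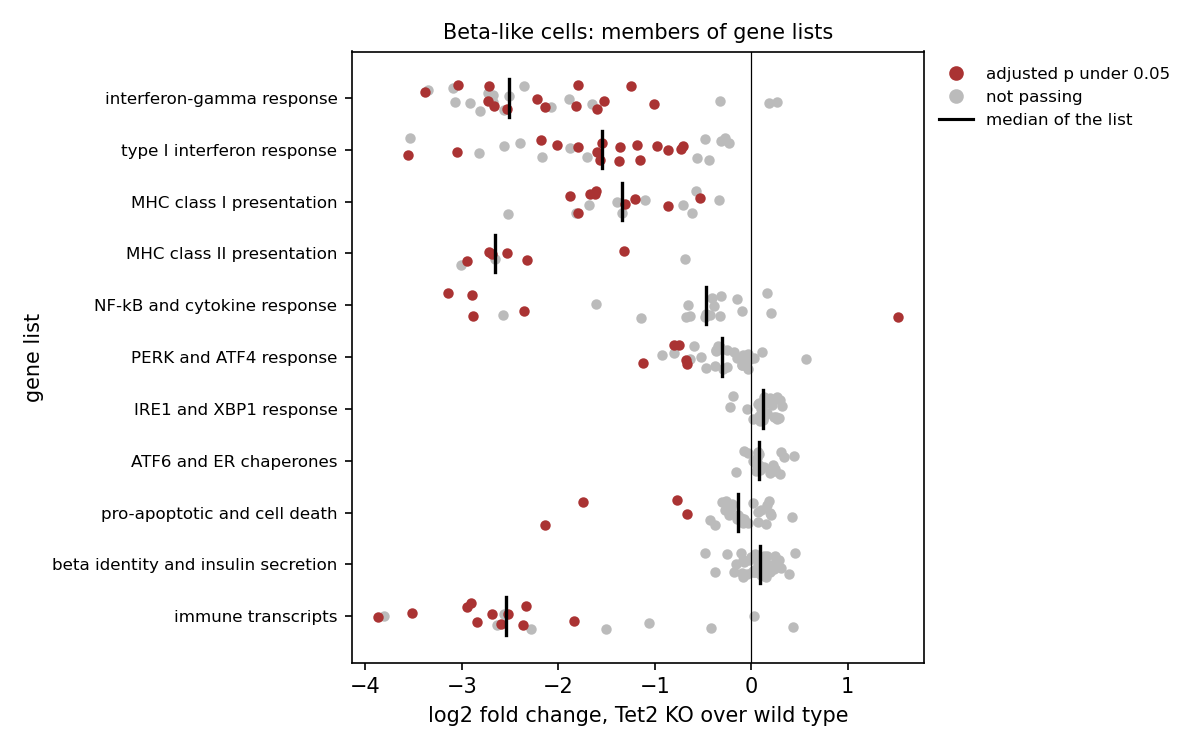
Log2 fold change, KO over WT, of each measured member of 11 gene lists in beta cells (red, adjusted p under 0.05; grey, not passing; black line, median). The medians of the interferon-gamma and MHC class II lists are -2.51 and -2.66, that of the PERK and ATF4 list -0.30, and those of the IRE1 and ATF6 lists 0.13 and 0.08 (-0.04 and -0.09 without TMM scaling, where the median of all genes was -0.146).

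Macrophages of KO islets changed in 305 of 9091 genes (121 higher, 184 lower; 3 against 3 libraries, at least 119 cells in each). Ly6a fell from 1961 and 2285 to 491 and 461 CPM in the 5' libraries and from 1100 to 233 in the 3' libraries (-2.13 ± 0.14, adjusted p = 1.6e-10), and its neighbour Ly6i by 1.88 ± 0.16 (adjusted p = 8.1e-08). The complement component C3 (-1.33 ± 0.14, adjusted p = 2.0e-06), the sterol receptor Nr1h3 (-1.29 ± 0.14, 2.4e-06), Plac8 (-2.08 ± 0.21, 2.9e-06) and Il18bp, which binds interleukin 18 (-1.15 ± 0.14, 2.5e-05), fell too. Apoe, a lipid carrier, rose from 4821 and 5863 to 10070 and 11480 CPM in the 5' libraries (0.93 ± 0.13, adjusted p = 0.00012). Rnase4 (1.71 ± 0.17, adjusted p = 1.4e-06), the elastase Mmp12 (1.83 ± 0.25, 9.3e-05), Phactr1 (1.87 ± 0.27), Cst3 (1.11 ± 0.15, 0.00012) and Il7r (1.61 ± 0.24) rose as well, and Ddhd1 fell (-1.50 ± 0.18). All 16 genes chosen by rank kept their calls without each library in turn. Phactr1 was also a leading gene of 3 clusters of beta cells. It did not pass without doublet removal (0.56), nor did Phactr1 (1.66) and Mmp12 (1.53) in the 5' libraries alone. The filter on genes more abundant in other classes left out Phactr1, Il7r and Plac8.

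Of 29 interferon-gamma response genes 15 fell in macrophages (24 adjusted over the list alone; median -0.66; adjusted p = 0.295 with an estimated correlation), with Gbp5 at -1.07 ± 0.17 (adjusted p = 0.00029) and Ifi47 at -0.77 ± 0.14 (0.0017). Of 29 type I interferon genes 6 fell (10 fell and 1 rose adjusted over the list alone; median -0.35; adjusted p = 0.548 with an estimated correlation), among them Irf7 (-1.12 ± 0.14, adjusted p = 2.7e-05) and Isg15 (-0.80 ± 0.14, 0.00092). Of 23 NF-kB and cytokine genes 6 fell (9 adjusted over the list alone; median -0.45; adjusted p = 0.453 with an estimated correlation), with Nfkb2 at -0.94 ± 0.17 (adjusted p = 0.0020). Of 27 inflammatory myeloid genes 4 fell (7 adjusted over the list alone; median -0.19; adjusted p = 0.529 with an estimated correlation): the chemokines Ccl5 (-1.18 ± 0.15, adjusted p = 0.00012) and Cxcl10 (-0.68 ± 0.14, 0.0045), Il18 (-0.93 ± 0.19, 0.0066) and Clec4e (-1.64 ± 0.39, 0.036). Il1b stood at 0.25 ± 0.13 (adjusted p = 0.393) and Cxcl9 at -0.47 ± 0.14 (0.0728), which passed without WT 3' (-0.70) or KO 3' (-0.70). Of 28 genes of resident and lipid-associated macrophages 3 rose and 1 fell, without a call of the list (median 0.08, camera adjusted p = 0.128). Apoe, Trem2, a lipid receptor (1.72 ± 0.24, adjusted p = 0.0059), and the scavenger receptor Cd36 (1.85 ± 0.39, 0.022) rose, and Timd4, a marker of resident macrophages, fell (-1.22 ± 0.26, 0.0086). MHC class I genes fell in 3 of 19 cases (11 adjusted over the list alone; median -0.34; adjusted p = 0.295 with an estimated correlation), such as H2-Q7 (-0.75 ± 0.14, adjusted p = 0.0022) and Tap1 (-0.55 ± 0.14, 0.018). None of 11 class II genes passed by edgeR (median 0.18, camera adjusted p = 0.219). Calls were lost without KO 5' set 1 for Ccl5 (-1.22), Il18 (-0.84), Clec4e (-1.14), Trem2 (1.6) and Timd4 (-0.87). They were lost without WT 5' set 1 for Cxcl10 (-0.57), Clec4e (-1.21), Cd36 (1.75) and Tap1 (-0.53), without WT 5' set 2 for Tap1 (-0.55) and without KO 5' set 2 for Clec4e (-2.0) and Tap1 (-0.49). Without WT 3' and without KO 3' they were lost for Timd4 (-1.31 and -1.31), Cd36 (1.71 and 1.72), H2-Q7 (-0.61 and -0.61) and Tap1 (-0.61 and -0.61).

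Beta cell transcripts were higher in the same KO macrophages. Of 17 beta identity genes 4 rose (7 adjusted over the list alone; median 1.41; adjusted p = 0.295 with an estimated correlation): Slc30a8 (2.96 ± 0.44, adjusted p = 0.0002), Cpe (2.16 ± 0.31, 0.00022), Scg3 (1.81 ± 0.37, 0.0041) and Cacna1d (1.07 ± 0.22, 0.0054). Scg3 lost its call without KO 5' set 1 (1.51), WT 3' (1.78) or KO 3' (1.79). The number of changed genes in macrophages was 185 without WT 5' set 1, 169 without WT 3', 148 without KO 3' and 137 in the 5' libraries alone. DESeq2 called 192.

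**Figure D4:**
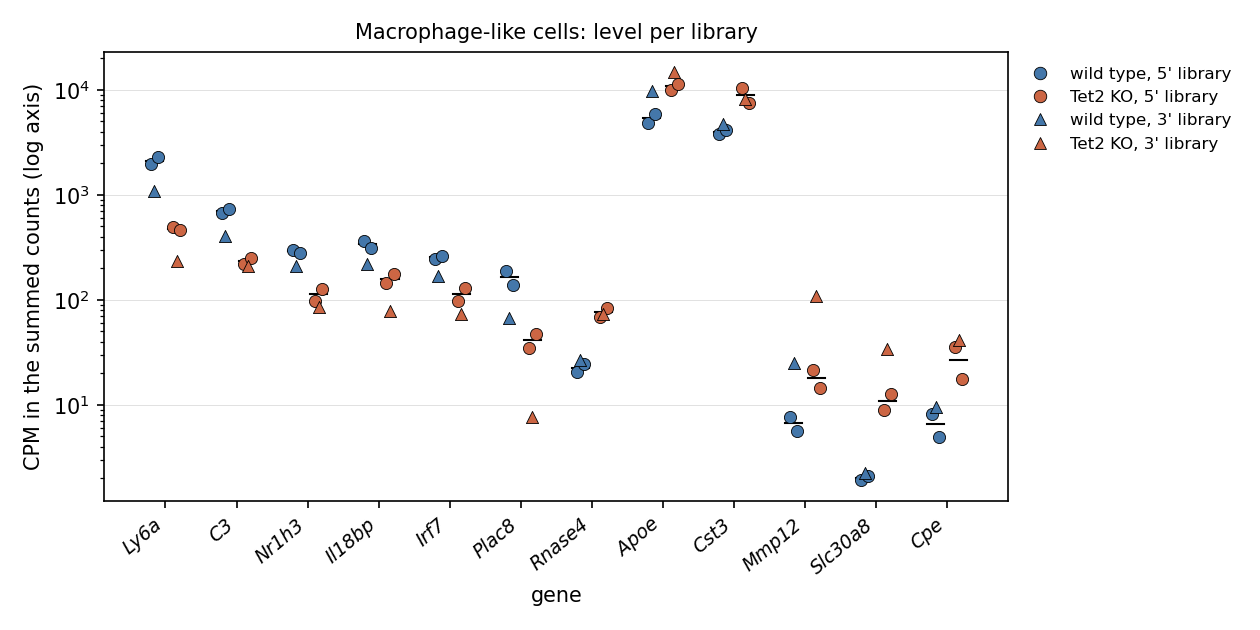
CPM of 12 genes in macrophages, on a log axis, for each library (blue, WT; orange, KO; circles, 5'; triangles, 3'; short black lines, mean of the 2 5' libraries of a genotype). Ly6a lies between 1100 and 2285 CPM in the WT and between 233 and 491 in the KO libraries.

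Few genes passed in CD8 T cells. Of 5773 genes tested in 3 against 3 libraries, with 37 cells in the smallest, Ccr8, a chemokine receptor, was higher (1.78 ± 0.34, adjusted p = 0.0432) and AY036118 was lower (-0.89 ± 0.15, 0.0163). AY036118 was named after its value was seen. Ccr8 was not on the same side in all libraries, and did not pass without WT 5' set 1 (1.57), WT 5' set 2 (1.83) or KO 5' set 1 (1.47). AY036118 did not pass without WT 5' set 2 (-0.85), KO 5' set 1 (-0.86) or WT 3' (-0.75). Itgae, an integrin that retains T cells in epithelia (1.08 ± 0.22, adjusted p = 0.0563), Nrgn (1.24 ± 0.23, 0.0563), Ccdc107 (1.27 ± 0.28, 0.0797) and Setbp1 (-0.97 ± 0.22, 0.0829) did not pass. Itgae passed without KO 5' set 2 (1.31) and Nrgn without WT 3' (1.5) or KO 3' (1.52). Gzmb, a cytotoxic protease, stood at -0.99 ± 0.33 (adjusted p = 0.662), Ifng at -0.14 ± 0.21, the checkpoint receptor gene Pdcd1 at 0.09 ± 0.21 and Tcf7, a factor of stem-like T cells, at -0.14 ± 0.21. Of 26 cytotoxic and effector genes 0 passed over all genes (1 rose and 2 fell adjusted over the list alone). The list was called lower (median -0.33, camera adjusted p = 0.0118, adjusted p = 0.62 with an estimated correlation), with Gzmk at -0.55 ± 0.18 (adjusted p = 0.552). The checkpoint and exhaustion list was also called lower (median -0.26 over 20 genes, camera adjusted p = 0.00166, adjusted p = 0.735 with an estimated correlation). Of its members 0 passed over all genes, and Havcr2 (-1.32 ± 0.40, adjusted p = 0.441) and Ctla4 (-0.55 ± 0.22, 0.677) had the lowest p. Beta identity transcripts had a median of 0.90 over 6 genes (adjusted p = 0.62 with an estimated correlation). By tool the count was 0 with DESeq2 and 7 with limma-voom. It was 1 without WT 5' set 2, 1 without KO 5' set 1, 15 without KO 5' set 2, 6 without KO 3' and 1 in the 5' libraries alone. By edgeR 342 genes had an unadjusted p under 0.05.

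In CD4 T cells, tested on the 4 5' libraries, edgeR called 0 of 5413 genes (371 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0). Those with the lowest p were Nrn1 (1.25 ± 0.23, adjusted p = 0.175), Chga, an endocrine granule transcript (1.77 ± 0.36, 0.245), Cmss1 (-0.71 ± 0.14, 0.245), Zc3h7a (-1.20 ± 0.27, 0.387) and Gpr183 (-1.08 ± 0.26, 0.429). Nrn1 (1.53) and Chga (1.73) passed without KO 5' set 2. Cmss1 passed without WT 5' set 1 (-0.96), KO 5' set 1 (-0.65) or KO 5' set 2 (-0.78). Ifng stood at 0.91 ± 0.43 (adjusted p = 0.706) and Tcf7 at -0.22 ± 0.16 (0.786). Foxp3, and Tet1 in each immune class named here, had too few counts to be tested. All 16 naive and stem-like genes had a negative fold change (median -0.23, camera adjusted p = 7.8e-05, adjusted p = 0.644 with an estimated correlation). Of these, 0 passed over all genes and 2 adjusted over the list alone. The lowest p were those of Lef1 (-1.15 ± 0.35, adjusted p = 0.668), which passed without KO 5' set 2 (-2.12), and Satb1 (-1.54 ± 0.48, 0.668). Leaving out 1 library left a genotype with 1 library, assumed to vary like the others, and gave 6 genes without WT 5' set 1, 5 without WT 5' set 2, 24 without KO 5' set 1 and 49 without KO 5' set 2.

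In regulatory T cells (5277 genes, 25 cells in the smallest library) Ctla2a rose (1.39 ± 0.24, adjusted p = 0.0035) and Satb1, a chromatin organiser of naive T cells, fell (-1.41 ± 0.25, 0.0048). Ctla2a lost its call without WT 5' set 1 (1.37), WT 5' set 2 (1.34) or KO 5' set 2 (1.12). Satb1 lost its call without these (-1.29, -1.56 and -1.15) or KO 3' (-1.30). Of their 16 naive and stem-like genes 1 fell (5 adjusted over the list alone; median -0.51; adjusted p = 0.176 with an estimated correlation). Of 23 interferon-gamma genes 0 passed (4 fell adjusted over the list alone; median -0.46; adjusted p = 0.176 with an estimated correlation). Klf3 of the first list stood at -2.05 ± 0.56 (adjusted p = 0.256), and Casp4 of the second at -0.97 ± 0.34 (0.402). The regulatory T cell count was 0 without WT 5' set 1, 0 without WT 5' set 2, 8 without KO 5' set 1, 6 without KO 5' set 2, 6 without WT 3', 4 without KO 3', 0 in the 5' libraries alone, 0 with DESeq2 and 7 with limma-voom. By edgeR 381 genes had an unadjusted p under 0.05.

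In B cells 4 of 9155 genes were higher and 1 lower (3 against 3 libraries, 47 cells in the smallest). Rora, a nuclear receptor, rose from 3.36 and 4.18 to 16.9 and 19.2 CPM in the 5' libraries (2.28 ± 0.36, adjusted p = 0.0131). The others were the endocrine transcripts Pcsk2 (2.37 ± 0.32, adjusted p = 0.0135) and Cltrn (2.98 ± 0.50, 0.0452), and the immunoglobulin segments Igkv15-103 (1.27 ± 0.24, 0.0452) and Igkv1-99 (-1.68 ± 0.29, 0.0194), named after their values were seen. Beta identity transcripts were higher as a list (median 1.65 over 23 genes, 1 rose, 12 adjusted over the list alone; adjusted p = 0.437 with an estimated correlation). B cell activation and germinal centre genes were called lower (median -0.42 over 20, camera adjusted p = 0.016, adjusted p = 0.766 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone. The lowest p were those of Ccr7 (-1.34 ± 0.28, adjusted p = 0.139), which passed without KO 5' set 2 (-1.64), and Fas (0.72 ± 0.27, 0.641). Dissociation and heat shock genes were called lower too, with all 20 negative (median -0.49; adjusted p = 0.557 with an estimated correlation). Cd86 stood at -0.78 ± 0.40 (adjusted p = 0.920) and Myc at -0.43 ± 0.55, and Cd86 passed without KO 5' set 2 (-1.22). When WT 5' set 1 was left out, Rora (2.22), Pcsk2 (2.13), Cltrn (2.99), Igkv15-103 (1.66) and Igkv1-99 (-1.42) lost their calls. Without WT 5' set 2 Cltrn (2.63), Igkv15-103 (0.97) and Igkv1-99 (-1.90) did. Without WT 3' and without KO 3' Rora (2.36 and 2.36), Igkv15-103 (1.28 and 1.27) and Igkv1-99 (-1.68 and -1.69) did. Igkv1-99 also did without KO 5' set 1 (-1.37). The count was 1 without WT 5' set 1, 23 without KO 5' set 1, 92 without KO 5' set 2, 11 with DESeq2 and 0 without doublet removal. Library totals without TMM scaling gave 5 higher and 3 lower genes.

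Alpha and delta (somatostatin) cells lost interferon transcripts as beta cells did. In alpha cells 30 of 12031 genes were higher and 162 lower (3 against 3 libraries). Il18bp (-1.88 ± 0.16, adjusted p = 3.8e-07), the interferon-induced GTPase gene Tgtp2 (-2.10 ± 0.19, 5.2e-07) and Col27a1 (-2.44 ± 0.23) led the fall. Cfi, a complement regulator (2.42 ± 0.38, 0.00046), Dab1 (1.00 ± 0.17) and Astn2 (0.84 ± 0.15) led the rise, the last without a call when WT 3' (0.75) or KO 3' (0.74) was left out. Cfi lies within 20 Mb of Tet2, and B6 DNA kept there was not tested as a source of its rise. Of 26 interferon-gamma genes 20 fell (24 adjusted over the list alone; median -1.75), such as Gbp8 (-1.96 ± 0.18) and Igtp (-1.85 ± 0.17). Of 24 type I genes 9 fell (19; median -0.85), such as Zbp1 (-2.50 ± 0.22) and Bst2 (-1.06 ± 0.15). Of 19 MHC class I genes 12 fell (17; median -1.22), such as H2-D1 (-1.28 ± 0.13) and Nlrc5 (-1.61 ± 0.17). Of 8 class II genes 4 fell (8; median -2.78), such as H2-DMa (-1.14 ± 0.18) and H2-DMb2 (-2.74 ± 0.38). Each of these lists had adjusted p = 0.0657 with an estimated correlation. Immune transcripts fell in 4 of 12 cases (10 adjusted over the list alone; median -2.54; adjusted p = 0.0657 with an estimated correlation), with Ptprc at -2.73 ± 0.45. The count was 109 without WT 5' set 1, 303 without KO 5' set 1 and 476 without KO 5' set 2.

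In delta cells 32 of 11806 genes were higher and 147 lower, and 10 higher and 126 lower without TMM scaling. Ifi47 (-1.94 ± 0.16, adjusted p = 3.1e-11), Oasl2 (-2.28 ± 0.19, 7.5e-11) and Gbp2 (-1.94 ± 0.15, 1.3e-10) fell, and Frmpd4 (1.07 ± 0.16) and Cntnap5b (0.81 ± 0.13) rose. Of 27 interferon-gamma genes 20 fell (23 adjusted over the list alone; median -1.51; adjusted p = 0.0126 with an estimated correlation). Of 28 type I genes 19 fell (24; median -1.16; adjusted p = 0.0224 with an estimated correlation). Of 19 MHC class I genes 15 fell (18; median -1.13; adjusted p = 0.0636 with an estimated correlation). Of 9 class II genes 2 fell (9; median -2.58; adjusted p = 0.103 with an estimated correlation). Parp14 (-1.11 ± 0.14), H2-Q4 (-1.18 ± 0.13), H2-T23 (-1.20 ± 0.14), Ciita (-2.67 ± 0.46) and H2-DMa (-1.23 ± 0.20) were among them. Of 41 beta identity genes 4 rose (5 adjusted over the list alone, median 0.12, adjusted p = 0.179 with an estimated correlation). They were Slc2a2 (1.25 ± 0.21, adjusted p = 9.3e-05), Nkx2-2 (0.72 ± 0.13), Slc30a8 (0.74 ± 0.15) and Ucn3 (1.11 ± 0.24). Slc30a8 lost its call without either 3' library (0.66 and 0.66), and Ucn3 without WT 5' set 2 (0.88) or KO 5' set 1 (0.90). Beta cell RNA as a source was not tested. Immune transcripts fell in 3 of 10 cases (5 adjusted over the list alone; median -2.0; adjusted p = 0.103 with an estimated correlation), with Coro1a at -2.42 ± 0.34 and Cd52 at -2.29 ± 0.31. The delta count was 311 without KO 5' set 2 and 118 with DESeq2.

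In endothelial cells 9 of 7770 genes were higher and 36 lower (3 against 3 libraries, 96 cells in the smallest). Of 31 interferon-gamma genes 13 fell (23 adjusted over the list alone; median -0.99; adjusted p = 0.144 with an estimated correlation), led by Iigp1 (-1.09 ± 0.15, adjusted p = 0.00035) and Irgm2 (-1.51 ± 0.23, 0.00092). Of 9 MHC class II genes 3 fell (6 adjusted over the list alone; median -1.20; adjusted p = 0.253 with an estimated correlation), with H2-Ab1 at -1.17 ± 0.17 and H2-DMb2 at -1.37 ± 0.23. Ttr, a transcript of endocrine cells, rose (3.88 ± 0.37, adjusted p = 2.2e-05), and Wars (-1.44 ± 0.16), H2-DMa (-1.72 ± 0.21) and Tgm2 (-1.64 ± 0.21) fell. Ccn3 (1.54 ± 0.30) and Sema5a (1.32 ± 0.26) rose, without a call when WT 3' (1.54 and 1.19) or KO 3' (1.54 and 1.19) was left out, and Ccn3 without one when WT 5' set 1 was (1.42). The count was 19 without WT 5' set 1, 106 without KO 5' set 2, 22 without WT 3', 23 without KO 3' and 19 in the 5' libraries alone.

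Mesenchymal cells changed in 535 of 7503 genes (229 higher, 306 lower; 38 cells in the smallest library). Il4i1, an enzyme that degrades amino acids (-3.04 ± 0.26, adjusted p = 2.2e-05), and Mfge8 (-1.97 ± 0.18) fell. The smooth muscle genes Acta2 (1.53 ± 0.17, 9.1e-05) and Myl9 (1.70 ± 0.19) rose. So did Rbp4 (2.33 ± 0.25). Endocrine RNA was not tested as its source. Of 22 NF-kB and cytokine genes 11 fell (15 adjusted over the list alone; median -1.02; adjusted p = 0.271 with an estimated correlation), with C3 at -1.89 ± 0.23 (adjusted p = 0.00034) and Icam1 at -1.72 ± 0.25 (0.00061). Of 19 MHC class I genes 11 fell (15; median -0.70; adjusted p = 0.179 with an estimated correlation), with H2-Q7 at -1.51 ± 0.21 and H2-K1 at -1.05 ± 0.17. The cell mixture differed between libraries: fibroblast-like clusters, with Dcn and C3 itself among their leading genes, held 60.5% and 72.6% of the mesenchymal cells of the WT 5' libraries against 26.7% (set 1) and 59.7% (set 2) of the KO ones, and 62.1% in WT 3' against 34.7% in KO 3'. Clusters led by Mgp, Acta2 and Rgs5 held the rest. In the fibroblast-like clusters alone 219 genes changed, 144 of them shared with the 535. There C3 (-1.17), Icam1 (-1.36), H2-Q7 (-1.12), H2-K1 (-0.86), Il4i1 (-2.74) and Rbp4 (2.08) passed, and Acta2 (-0.50), Myl9 (0.61) and Mfge8 (-2.48) did not. The mesenchymal count was 200 without WT 5' set 2, 297 without WT 3', 306 without KO 3' and 262 in the 5' libraries alone.

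**Figure D5:**
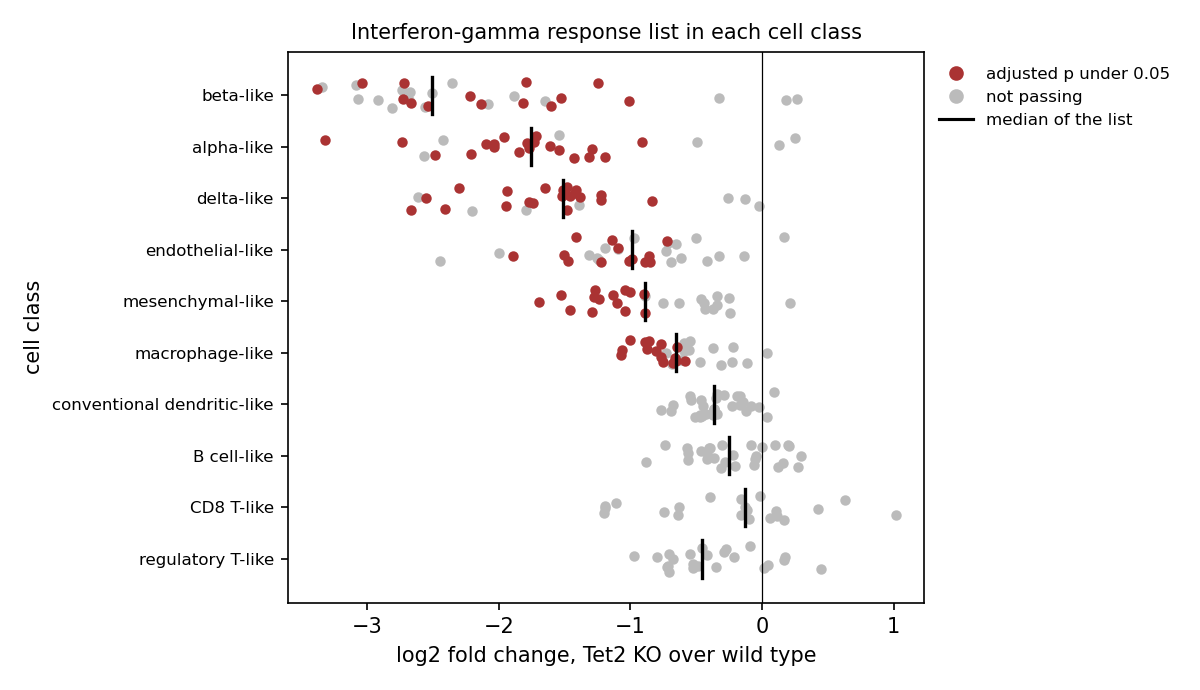
Log2 fold change, KO over WT, of each measured gene of the interferon-gamma response in 10 cell classes (red, adjusted p under 0.05; grey, not passing; black line, median). The median is -2.51 in beta, -1.75 in alpha, -1.51 in delta and -0.99 in endothelial cells, -0.66 in macrophages and -0.25 in B cells.

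In conventional dendritic cells 19 of 8748 genes were higher and 11 lower, and 12 higher and 22 lower without TMM scaling. The complement factor Cfb (-0.87 ± 0.16, adjusted p = 0.0053), Rest (-0.96 ± 0.18) and Irf7 (-0.80 ± 0.15) fell. These 3 calls were lost without WT 5' set 1 (-0.88, -0.98 and -0.76) and without WT 5' set 2 (-0.79, -0.97 and -0.76). Cfb (-0.81) and Irf7 (-0.71) also lost theirs without KO 5' set 1, and Rest without WT 3' (-0.92) or KO 3' (-0.92). Of 26 type I interferon genes 3 fell (11 adjusted over the list alone; median -0.40; adjusted p = 0.309 with an estimated correlation). The genes with the lowest p among those that rose were the endocrine transcripts Ptprn2 (2.83 ± 0.32, adjusted p = 2.7e-05), Pcsk2 (1.91 ± 0.24) and Cpe (2.12 ± 0.30), and 5 of 14 beta identity genes rose (5 adjusted over the list alone; median 1.36; adjusted p = 0.271 with an estimated correlation). Ptprn2, Pcsk2 and Cpe lost their calls without WT 3' (1.98, 1.57 and 1.58) or KO 3' (1.99, 1.58 and 1.58). The count was 14 without WT 5' set 1, 14 without WT 5' set 2, 171 without KO 5' set 2, 9 without WT 3', 5 without KO 3' and 5 in the 5' libraries alone.

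The smaller classes were tested on the 4 5' libraries. In cycling T cells 4 of 8467 genes fell: Lgals3 (-1.42 ± 0.18, adjusted p = 0.0092), Ctla2a (-1.66 ± 0.21, 0.0092), the chemokine receptor gene Cxcr6 (-1.54 ± 0.21, 0.011) and Satb1 (-1.82 ± 0.27, 0.020). Cxcr6 did not pass without KO 5' set 1 (-1.38). These cells came from a pair of clusters whose mixture differed by genotype: 1 held 285 and 144 cells of the WT and 25 and 38 of the KO libraries, the other 230 and 188 against 121 and 74. Genes were not tested within each cluster, so no value of this class is shown to be a change within 1 kind of cell. Cytotoxic genes were called lower (median -0.73 over 26, 1 fell, 5 adjusted over the list alone; adjusted p = 0.706 with an estimated correlation). The regulatory T cell program had a median of 0.46 over 17 genes (0 passing, 5 rose and 1 fell adjusted over the list alone). Areg stood at 2.71 ± 0.45 (adjusted p = 0.059) and Foxp3 at 1.23 ± 0.24 (0.15). Areg passed without KO 5' set 2 (3.14) and Foxp3 without WT 5' set 2 (1.37). Other T cells had 1 higher gene, mt-Atp6 (0.62 ± 0.10, adjusted p = 0.0017), named after its value was seen and not passing without WT 5' set 2 (0.54). In cycling B cells 9 of 8296 genes fell, 8 immunoglobulin segments and Ins1 (-1.15 ± 0.17, adjusted p = 0.025), which did not pass without KO 5' set 2 (-0.93), without doublet removal (-0.78) or with limma-voom (-1.13). In plasma cells 5 immunoglobulin segments were higher and 2 lower. Gcg, the glucagon transcript of alpha cells, was at 12.3 and 25.9 CPM in the WT and 5115 and 4309 in the KO libraries (8.19 ± 0.53, adjusted p = 0.00057). Alpha cells were 4.08% and 4.47% of the WT and 13.1% and 11.1% of the KO libraries. Gcg did not pass without doublet removal (1.11), and the filter on genes more abundant in other classes left it and Ins1 out. Without TMM scaling the median of all genes there was -0.266, against -0.0056 with it. In NK/ILC cells edgeR called 0 of 1315 genes (69 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0). Without WT 5' set 1, WT 5' set 2, KO 5' set 1 and KO 5' set 2 in turn, counts were 34, 49, 5 and 39 in cycling T cells, 8, 4, 8 and 22 in other T cells, and 74, 44, 11 and 19 in cycling B cells. They were 25, 32, 43 and 72 in plasma cells, and 3, 4, 8 and 8 in NK/ILC cells.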

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

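The tests of explanations in this part were chosen after the patterns they bear on had been seen, the difference between chemistries and the search of unnamed clusters included, whereas the count of other splits of the libraries was planned.

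The first pattern is the fall of interferon and antigen presentation genes in KO beta cells. RNA of immune cells in beta cell droplets was tested as its source by setting each gene's fall against its level in immune cells. Such RNA brings every immune transcript at 1 ratio, and the median fall over 20 immune transcripts was 0.310% of their level in immune cells. It was 9.15% over MHC class I genes (29.5 times as much), 22.7% over interferon-gamma genes (73.2 times) and 16.9% over type I interferon genes (54.6 times), which argues against it for these lists. It was 0.785% over MHC class II genes, 2.54 times the 0.309% of 19 immune transcripts, also above the bound of 2 set beforehand (one-sided permutation p = 3e-04). This argues against such RNA as the whole source here, but part of the fall may come from it. RNA of non-immune cells was not tested.

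Less immune infiltrate in the KO pools, whatever the genotype of the islet cells, remains open. Within a genotype the 5' library with more immune cells had the higher mean level of the interferon-gamma list in 1 of 2 pairs: 4.01 at 77.3% immune cells against 3.28 at 63.6% in WT, but 1.69 at 26.7% against 2.11 at 20.7% in KO. With 2 pairs, and immune share bound to genotype, an effect of Tet2 in beta cells and a lower exposure to immune cells cannot be told apart.

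As a second pattern, the changed beta cell genes were weighed against B6 DNA kept around Tet2 in the backcross. Of the 314 genes, 1.91% lie within 20 Mb of Tet2 (Vcam1, Tifa, Bank1, Gbp5, Gbp7 and Gbp2b), against 1.11% of the genes tested (two-sided Fisher exact p = 0.165). This is under the 10% set beforehand, so most changed genes lie elsewhere. Position cannot tell whether B6 alleles near Tet2 acted on them, so such DNA remains open.

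The third pattern is the rise of beta cell transcripts in KO macrophages. Over the 10 beta identity genes higher there at an unadjusted p under 0.05, the log2 ratio of macrophage to beta cell level in KO had an interquartile range of 0.879, under the bound of 2 set beforehand. For 9 of them the ratio lay between -5.41 and -3.67, and Cacna1d stood apart at -0.64. Of the 9, Ero1lb was already at 37.4 CPM in WT macrophages and at 55.3 in KO (log2 0.43), so its ratio mostly reflects a level present in WT. Free RNA of endocrine cells is a candidate source for the other 8, but doublets with beta cells or uptake of beta cell material would keep the same ratio, and this test does not separate the 3.

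In beta cells the effect of KO was tested for a difference between chemistries by an interaction term in edgeR, and 10 of 14288 genes passed (638 at an unadjusted p under 0.05). The differences, 3' minus 5' libraries, were -5.55 for Jchain (adjusted p = 0.0018), -9.78 for Slpi (0.0022), -2.40 for Dbp (0.0022), -1.91 for 3830406C13Rik (0.0093) and -2.01 for Fmo1 (0.011). They were -2.01 for Nr1d1 (0.013), -10.38 for Ighg1 (0.013), -1.85 for Rbm3 (0.037), 2.89 for Spp1 (0.044) and -1.50 for 2410021H03Rik (0.050). The clock genes Dbp (0.57 in 5', -1.67 in 3') and Nr1d1 (0.47 and -1.37) had opposite signs in the 2 chemistries. Slpi and Ighg1 were at 0 in KO 3' (4.66 and 11.7 CPM in WT 3'), so their fitted folds are no bounds. With 1 library per genotype in 3', the spread behind these p-values comes from the 5' pairs alone, and the 3' libraries are assumed to vary alike. A difference of chemistry and one of pools are the same contrast here, and no explanation was tested.

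Some clusters that no marker set named were concentrated in 1 KO library, at 50 or more cells and 10 or more times the highest percent of a WT library, limits chosen after the clusters had been seen. In KO 5' set 2, a cluster led by AY036118 and Il1rapl1 held 11.09% of kept cells (highest WT library 0.522%), 1 led by Lars2 and Gphn 4.56% (0%), 1 led by Glycam1 and Lrg1 1.313% (0.0764%) and 1 led by Clec3b and Mfap5 0.518% (0%). In KO 5' set 1, a cluster led by Fabp2 and Apoa1 held 2.374% (0.0139%), and a group of T or innate lymphoid cells led by Gzma and Gzmb 0.7409% (0.0278%). In KO 3', a cluster led by Apoa1 and Prap1 held 0.79% (0%). Median UMIs were 1300 and 1348.5 in the first 2 clusters, against 3314 over that library. No explanation was tested for these cells.

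Chance was weighed by counting the 10 splits of the 6 libraries into 3 and 3, which cannot give a share under 0.05. The real split gave 314 genes in beta cells, with 1 as the highest of the others, 305 and 2 in macrophages, 192 and 5 in alpha cells, and 179 and 2 in delta cells. It gave 535 and 0 in mesenchymal cells, 45 and 4 in endothelial cells, and 30 and 14 in dendritic cells, in each of these 7 classes with 1 split of 10 as large. In CD8 T cells the real split gave 2 and the highest other 38 (6 of 10 as large), in B cells 5 and 44 (6 of 10), and in regulatory T cells 2 and 14 (5 of 10). For gene lists in beta cells it gave 16 and the highest other 22 (3 of 10). The highest other counts in CD8 T, B, regulatory T and dendritic cells came from 1 split, which sets 5' set 1 of both genotypes with KO 3' against 5' set 2 of both with WT 3'. Several times the real count in the first 3 classes, they point to a structure of the libraries other than genotype. The split that parts the same 5' sets with the 3' libraries exchanged gave 4, 5, 4 and 10.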

How the results depend on the processing

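Most alternatives in this part were planned, and 5 were chosen after seeing the data: beta cells with a low-count cluster, CD4 T cells with a further cluster, the free RNA filter that also looks at unnamed clusters, the fibroblast-like mesenchymal clusters, and the gene lists in beta cells without UMIs of other classes. For 235 genes chosen by the rule and 4165 pairs of gene and setting, the direction and the side of the threshold held in 3634, the call was lost in 423, gained in 79, and the direction reversed in 29. For 30 gene lists in beta cells these numbers were 278, 17, 32 and 1 of 328. For shares they were 319, 54, 11 and 6. Counts of changed genes stayed within 1.5 times in 124 cases and moved further in 150, and the count of called lists in 11 and 2. Unless a cause is given, the cause was not tested.

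The 12 lower genes with the lowest p in beta cells kept their calls with DESeq2, limma-voom, no TMM, the 5' libraries alone and both cell filters. Of all 24 genes chosen by rank there, 15 passed without TMM, 14 in the 5' libraries alone and 15 without doublet removal. The free RNA filter left 8 of the 24 to be tested, of which 7 passed. Of the 12 lower ones it left only H2-T22 and Tifa. In beta cells without UMIs of other classes 18 of the 24 could be tested and 8 passed. With the low-count cluster added 19 passed. Of the 16 such genes in macrophages 15 passed with DESeq2 (Slc30a8 lost).

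DESeq2 gave 0 genes in CD8 T, 11 in B, 0 in regulatory T and 16 in dendritic cells and 192 in macrophages. It gave 118 in delta, 344 in mesenchymal, 2 in other T, 17 in cycling B and 30 in plasma cells. With limma-voom the counts were 7 in CD8 T, 1 in B and 7 in regulatory T cells. They were 2 each in other T, cycling B and plasma cells. No TMM gave 4 in CD8 T, 8 in B, 5 in regulatory T, 1 in NK/ILC and 2 in other T cells.

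No low-count filter gave 681 in beta, 25 in CD8 T, 12 in CD4 T and 55 in B cells and 539 in macrophages. It gave 12 in regulatory T, 170 in dendritic, 466 in alpha, 288 in delta, 142 in endothelial and 995 in mesenchymal cells. It gave 6 in NK/ILC, 7 in other T, 71 in cycling T, 67 in cycling B and 111 in plasma cells.

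The 5' libraries alone gave 200 in beta, 1 in CD8 T, 0 in regulatory T and 5 in dendritic cells and 137 in macrophages. They gave 19 in endothelial and 262 in mesenchymal cells. This setting has fewer samples. Share calls lost were those of CD8 T (-1.43), dendritic (-1.06), cycling beta (1.45), NK/ILC (-1.27) and regulatory T cells (-1.13). Among immune cells that of B cells (-0.63) was lost. Cycling B cells among immune cells, not called either way, stood at 0.23.

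The replicate block, with chemistry and set number together, gave 18 in CD8 T, 28 in B and 41 in regulatory T cells. It gave 151 in dendritic, 363 in alpha, 71 in endothelial, 1 in NK/ILC and 3 in other T cells. In cycling T, cycling B and plasma cells it gave 39, 28 and 27. Shares of alpha (1.19), dendritic (-1.20), cycling beta (1.73), NK/ILC (-1.32) and regulatory T cells (-1.63) lost their calls. So did B cells among immune cells (-1.10). The differences of the 2 5' sets in WT and KO correlated at 0.307 in beta cells, 0.147 in CD8 T cells, 0.202 in B cells and 0.249 in macrophages. Of named genes, B2m (-1.86), Nnat (1.30), Chac1 (-0.74) and Tnfrsf11b (1.45) in beta cells and mt-Atp6 (0.62) in other T cells were not called. Chgb (beta), Itgae, Nrgn, Ccdc107, Setbp1 (CD8 T), Cxcl9 (macrophages), Klf3 (regulatory T), Ccr7 (B), Areg and Foxp3 (cycling T) gained calls. The labels do not tie equal set numbers to a shared day or litter. With 2 pairs these values are a hint and not a part of the design, so the unblocked test was kept.

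A mitochondrial limit of 10% gave 7 in CD8 T, 0 in B, 1 in NK/ILC and 0 in other T cells. At 500 or more genes per cell 1 gene passed in B cells, and the shares of beta cells (1.06) and endothelial cells (1.18) passed. Without doublet removal 124 genes passed in beta, 1 in CD8 T, 16 in CD4 T, 0 in B and 79 in dendritic cells. In endothelial, mesenchymal, other T, cycling T and plasma cells 70, 810, 9, 20 and 4 passed. The shares of beta cells (1.10) and, among immune cells, of dendritic cells (0.87) and plasma cells (0.94) then passed. Cycling beta cells (0.59) did not, and mesenchymal cells (-0.26, not called) changed sign. Leiden resolution 2.0 gave 1 in CD4 T, 1 in B, 1 in NK/ILC and 6 in other T cells. There the beta share (1.11) passed and B cells among immune cells (-1.05) did not. TMM over classes called the shares of beta (1.61), delta (1.18) and endothelial cells (1.76) and no longer those of dendritic cells (-0.73), NK/ILC cells (-0.83) and regulatory T cells (-1.15).

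The free RNA filter, which tests fewer genes, gave 83 in beta, 8 in CD8 T, 1 in CD4 T and 2 in B cells. It gave 4 in regulatory T, 4 in NK/ILC, 6 in other T and 1 in cycling B cells. With unnamed clusters counted it gave 78, 8, 1, 2, 5, 4, 6 and 1 in the same order. Beta cells without UMIs of other classes gave 59 genes and beta cells with the low-count cluster 114, and the fibroblast-like clusters 219 in mesenchymal cells. Camera with an estimated correlation called 0 lists in beta cells and fry 0, against 16 by camera with the preset correlation.

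With each library left out in turn, counts ranged from 121 to 470 in beta cells, 1 to 15 in CD8 T cells, 5 to 49 in CD4 T cells, 1 to 92 in B cells, 148 to 380 in macrophages, 0 to 8 in regulatory T cells and 5 to 171 in dendritic cells. They ranged from 109 to 476 in alpha cells, 149 to 311 in delta cells, 19 to 106 in endothelial cells, 200 to 637 in mesenchymal cells, 3 to 8 in NK/ILC cells, 4 to 22 in other T cells, 5 to 49 in cycling T cells, 11 to 74 in cycling B cells and 25 to 72 in plasma cells.

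Share ratios with each library left out ranged from 1.04 to 1.5 for alpha cells, -3.70 to -2.24 for B cells, -2.80 to -1.80 for CD4 T cells, -2.01 to -1.43 for CD8 T cells, -1.43 to -1.03 for dendritic cells and -3.55 to -1.29 for cycling B cells. They ranged from 1.44 to 2.04 for cycling beta cells, -2.32 to -1.87 for cycling T cells, 1.21 to 3.50 for ductal cells, -1.54 to -1.13 for NK/ILC cells and -1.89 to -1.13 for regulatory T cells. Among immune cells they ranged from -1.33 to -0.63 for B cells, -1.22 to 0.23 for cycling B cells and 1.13 to 1.68 for macrophages. Cycling B cells among immune cells changed sign without WT 3' (0.23) or KO 3' (0.23). Acinar cells, not called, ranged from -0.46 (without KO 5' set 2) to 1.65 and stood at -0.12 without WT 5' set 1.

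Among these genes, of those that reversed, Acta2 in mesenchymal cells alone had a call, and stood at -0.50 in the fibroblast-like clusters and at 1.44 to 1.6 with a library left out. That setting leaves out the clusters led by Acta2, which shows the cause. The other genes that reversed had no call either way. Txnip in beta cells stood at 0.0098 without a filter on low counts and at 0.0255 in beta cells without UMIs of other classes, and ranged from -0.17 to 0.21 with a library left out (0.21 without WT 5' set 2, 0.08 without KO 5' set 1). In beta cells Tet1 stood at 0.12 without UMIs of other classes (-0.21 to -0.14 with a library left out) and Pdx1 at -0.051 without TMM, where the median of all genes was -0.146 (-0.0127, without KO 5' set 1, to 0.26 with a library left out). Tet2 ranged from -0.22 to 0.0629 (without KO 5' set 1). Tet3 ranged from -0.27 to 0.10, and was 0.10 without WT 5' set 2, 0.07 without KO 5' set 1, 0.01 without WT 3' and 0.00 without KO 3'.

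In CD8 T cells Ifng ranged from -0.31 to 0.0812 (without WT 5' set 1), Tet3 from -0.84 to 0.27 (without KO 5' set 1) and Pdcd1 from -0.11 (without WT 5' set 1; -0.08 without KO 5' set 1) to 0.38. Tcf7 there ranged from -0.35 to 0.0719 (without KO 3'; 0.06 without WT 3') and was 0.0717 in the 5' libraries alone. In CD4 T cells Tet2 ranged from -0.76 to 0.48 (without WT 5' set 2; 0.24 without KO 5' set 1), and was 0.034 without doublet removal and 0.26 with the further cluster. In B cells Tet2 was 0.0162 at Leiden resolution 2.0 and ranged from -0.64 to 0.0233 (without KO 5' set 1), and Myc ranged from -1.03 to 0.17 (without WT 5' set 2). In macrophages Tet2 ranged from -0.29 to 0.15 (without KO 5' set 1; 0.03 without WT 5' set 1). The list of dedifferentiation genes in beta cells, not called in the report, was called higher (0.35) in cells without UMIs of other classes, and stood at -0.40 to -0.16 with a library left out.

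The library with the fewest counts held 56359 in regulatory T cells, 73001 in CD8 T cells and 76649 in B cells against 17719100 in beta cells. In simulated data with 200 changed genes the test made 127 calls in regulatory T and 138 each in CD8 T and B cells. It recovered 88%, 85% and 84% of 4-fold changes there but 36%, 46% and 48% of 2-fold ones (79% in beta cells). So depth remains open for smaller changes.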

Other observations

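No test in this part was planned, and the values below were chosen after they had been seen.

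A cluster led by Ppy, Pyy and Folr1 held 69 cells in WT 3' and 271 cells in KO 3' (3.51% of that library, against 0.645% in WT 3'). It was left without a class, and cells of pancreatic polypeptide were not compared. A 5' group of T or innate lymphoid cells led by Ifit1, Ifit3 and Isg15 held 70 and 23 cells in the WT libraries and 6 and 7 in the KO libraries. These counts were not tested.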
